A study of Eutrema salsugineum with 12 samples.

How the data were processed

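RNA from guard-cell-enriched leaf samples of Thellungiella salsuginea was measured on 12 Agilent 1-colour arrays, 4 from watered control plants, 4 from plants given 1 salt treatment (1x salt) and 4 from plants given 3 (3x salt). Groups and replicate numbers were taken from the sample titles. The arrays lay on 3 slides, each scanned in 1 session, so slide and scan coincide. Slide 1 held 2 arrays of 1x salt and 1 of 3x salt. Slide 2 held 3 control arrays and 2 of 3x salt. Slide 3 held 1 control array, 2 of 1x salt and 1 of 3x salt.

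Per the file headers, the deposited scanner output gives spot intensity on a linear scale, background-subtracted and detrended within each array by Agilent Feature Extraction and not normalized between arrays. Per the submitters' processing notes, Agilent Feature Extraction 11 and limma were used. Mean spot intensity and local background intensity per the file headers were used for an alternative background correction. The authors' series table holds log2 values with nearly identical distributions in all 12 columns. Its column medians ran from 8.38 to 8.40, each column followed its own array with a correlation across contigs of at least 0.976, and how its background was corrected is not given in the sources used here. It served only as an alternative.

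Each array carried 43800 different probes of 60 bases, which stand for 41563 assembled transcript sequences (contigs and sequence clusters, both called contigs here). Of these contigs, 2237 had 2 probes and the others had 1. The files pair 0 contigs with a gene name or description, and the reference table of gene loci used here shares no identifier with them. The gene lists, cell type markers and genes of interest that had been fixed before the data were examined therefore matched 0 contigs and were not tested. Contigs are given by their array name, for at most 2 that rose and 2 that fell.

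In place of the gene lists, each probe was translated in 6 reading frames and searched for 119 short peptide signatures of well-known protein families. The signatures were written after the array's names had been seen and before any expression value was set against a group. Of the 60 with a match, 9 were dropped because they also matched the strand opposite to the probes, and 51 were kept. Over all signatures there were 222 matches on the sense strand and 12 on the antisense strand. Of the contigs tested, 174 carried a kept signature, in 38 families. The 21 families with at least 3 contigs were tested, and 17 had 1 or 2 contigs. A probe of 60 bases encodes about 20 residues, so a family is described as contigs whose probe encodes its signature. Matches were kept even where the translated probe holds a stop codon, and the family of such a contig is less certain. Families are incomplete, several contigs can come from 1 gene, and a family's contigs are not independent.

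Spot signals of a probe were averaged on the log2 scale after outlier spots were left out. The value used throughout is log2 of the processed intensity minus the array's 75th percentile over non-control probes. Probes were kept where they were well above background on at least 4 of the 12 arrays, which kept 39150 and removed 4650. A contig with 2 kept probes was represented by the brighter. This left 37210 contigs. The 75th percentile of the signal lay between 1034 and 1553 units, between 87.3% and 89.7% of probes were well above background on each array, and 0 spots were saturated. Arrays have no read depth, and their number limits the precision. Replicated spots of a probe differed on an array by a median SD of 0.0375 (log2). The median SD over contigs between arrays of a group was 0.140 in the controls, 0.230 in 1x salt and 0.127 in 3x salt. Every pair of arrays within a group differed by more than the replicated spots (at least 0.153, against 0.053 for a difference of 2 arrays), so no array copied the values of another. Spots on 1 array carry no labelling or hybridization error, so this does not tell separate RNA from repeated arrays of 1 RNA, and all 12 were counted as separate samples because the labels list them so. The labels do not say whether the samples of a group came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical in part.

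limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group over all 12 arrays, with no block and with the spread of a contig pooled over all groups. The contrasts were tested with its moderated statistics, two-sided, and adjusted by the Benjamini-Hochberg method over the 37210 contigs of each contrast at a threshold of 0.05. Families were tested with limma's camera at a preset correlation of 0.01, adjusted over 63 tests, with fry as another test and camera again with an estimated correlation. Where all 4 arrays of a group were not well above background for a contig, the fold is given as a lower bound: the bright group's mean against the mean of the higher of the lowest signal well above background on each array and the contig's own signal. This bound rests on the main values and on that floor, and the change under another background correction can be smaller. The floor is not a detection limit, since probes not well above background could be brighter than it. For example, thellun_all_c20617 lay at -6.85 in 3x salt replicate 2 without being well above background. A fold given as at least a value is thus relative to the floor and not a strict limit. Named contigs follow the rule fixed before the data were examined, without its clause on descriptions: adjusted p under the threshold, 4 values of the higher group all above the 4 of the lower, well above background on all 4 arrays of the higher group, and then the largest fitted changes, which rank contigs at background only roughly. The rule's 8 rises and 8 falls per contrast are given as ranges, with bounds apart from measured changes. Family members named in the text were chosen after their values were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for translation, tables and plots.

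The code was tested on simulated data with 200 of 37199 contigs changed. At a simulated log2 change of 1, 75.5% were recovered for 1x salt against control, 77.5% for 3x salt against control and 78.0% for 3x against 1x salt. At 0.5 the shares were 10.0%, 8.5% and 0%. These shares hold for 200 changed contigs and equal spread in all groups. They do not carry over to the comparisons with control, where many more contigs passed. For a family of 10 contigs in 3x salt against control, camera found 100% of the simulated shifts of 0.5 and 2% of unshifted families in 50 draws. These contigs were drawn independently, whereas estimated correlations within the tested families ran from 0.04 to 0.87. The 2% is therefore not an error rate for families with correlated contigs.

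Alternatives covered quantile and median scaling, normexp background correction with an offset of 50, the authors' table, the filter on dim probes, the slide as a fixed or random block and within each slide, the replicate number as a block, the mean of a contig's probes, array weights, robust moderation, the 8 arrays of a contrast alone, a fold threshold, an estimated correlation, and each array left out in turn. After the data were seen, fits without the pair of 1x salt arrays on slide 3 or the pair on slide 1 were added. No scaling moved the share of higher calls by over 10 percentage points or the median of all contigs by over 0.1 (log2). The size of the excess of rises over falls against control nevertheless depended on the scaling.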

Results

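Thellungiella salsuginea, a salt-tolerant relative of Arabidopsis, was grown in soil for 7 weeks under 12 h of light at 22 °C and nights of 16 °C. Pots of the 3x salt group stood for 2 h in 75 mM NaCl on days 1 and 2, in 150 mM on days 7 and 8 and in 200 mM on days 13 and 14. The 1x salt group received 200 mM on days 13 and 14 alone, and the control group received tap water. Guard-cell-enriched samples, which are preparations rich in the cells that open and close the leaf pores, were taken on day 15 from plants kept in light for 4 h. Each group had 4 samples on 1 array each. The comparisons ask how the guard cell transcriptome differs after a short salt exposure, after a repeated one, and between them. Array contigs carry no gene names, so groups of contigs are named by the protein signature that their probe encodes.

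The first principal component held 36.4% of the variance and set the controls, between -75.5 and -37.5, apart from the 8 salt arrays, between 10.1 and 47.6. The second held 21.4% and parted the 1x salt arrays by slide, with 77.8 and 29.4 on slide 3 and -60.1 and -39.7 on slide 1. The control array of slide 3, replicate 4, lay nearest to the salt arrays.

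**Figure D1:**
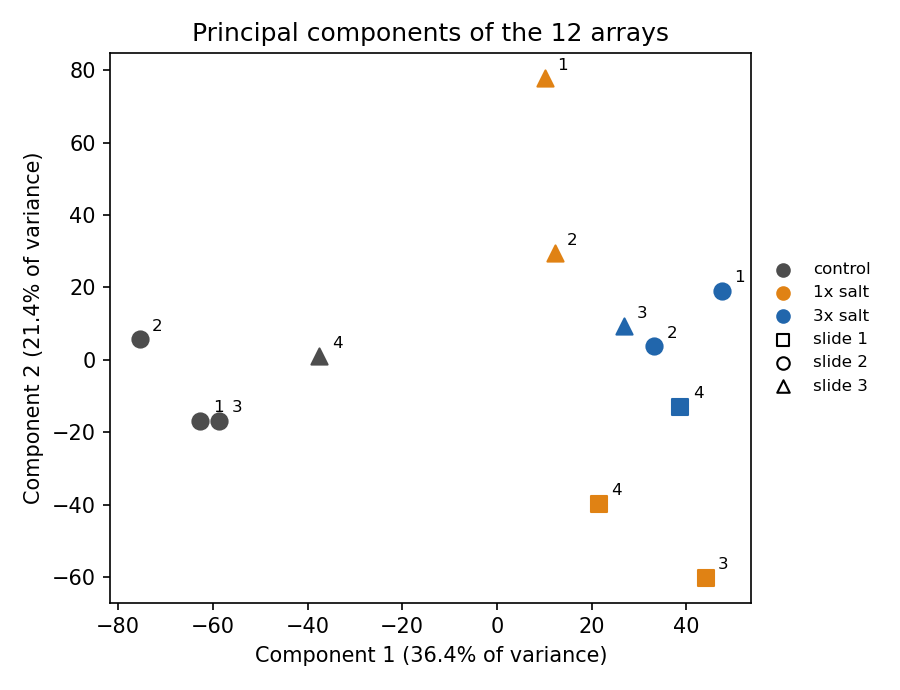
The first component (36.4% of variance) is on the x axis and the second (21.4%) on the y axis, in arbitrary units, with 1 point per array, coloured by group, shaped by slide and numbered by replicate. The 4 controls lie between -75.5 and -37.5 on the x axis, the 8 salt arrays between 10.1 and 47.6, and the 1x salt arrays spread from -60.1 to 77.8 on the y axis.

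In 1x salt against control, contigs that encode calcium-binding EF-hand loops, the loops with which calmodulins and related sensors bind calcium, were lower. Of 14 such contigs, 7 fell, 1 rose and 6 did not pass, with a median log2 fold change of -0.51 and the family's median below every control on 4 of 4 arrays (limma's camera, adjusted p = 0.00149, and adjusted p = 0.621 with an estimated correlation). The lowest was the contig that encodes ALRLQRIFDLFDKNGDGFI, which fell by 1.61 (SE 0.20, limma adjusted p = 0.00235, lower in 4 of 4 arrays). The contig that encodes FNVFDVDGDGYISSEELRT rose by 0.74 (SE 0.20, limma adjusted p = 0.0343, higher in 4 of 4 arrays). Sugar transporter contigs, with the PESPRWL signature of carriers that move sugars across membranes, had the lowest family median, -1.62, below every control on 4 of 4 arrays (limma's camera, adjusted p = 0.0102, and adjusted p = 0.434 with an estimated correlation). Of 3, 2 fell and 1 did not pass. The contig with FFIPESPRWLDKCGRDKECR had a log2 fold change of -1.72 (SE 0.31) and that with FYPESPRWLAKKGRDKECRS one of -1.62 (SE 0.26), both lower in 4 of 4 arrays.

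Protein kinase contigs, which encode signatures of the kinase domain, were also lower in 1x salt, with 3 of 8 having fallen, 0 risen and a median of -0.42, below every control on 4 of 4 arrays (limma's camera, adjusted p = 0.00318, and adjusted p = 0.434 with an estimated correlation). Of 3 contigs of tubulins, the building blocks of microtubules, 2 fell, and the median was -0.45, below every control on 4 of 4 arrays (limma's camera, adjusted p = 0.0438, and adjusted p = 0.621 with an estimated correlation). The 18 contigs of chlorophyll a/b-binding proteins, the antenna proteins of chloroplasts, had a median of -0.16, below every control on 3 of 4 arrays (limma's camera, adjusted p = 0.00732, and adjusted p = 0.873 with an estimated correlation). None of the 18 passed limma on its own, and 1 was lower at an unadjusted p under 0.05. The 27 contigs of ubiquitin, the tag for protein breakdown, had a median of +0.18, above every control on 2 of 4 arrays (limma's camera, adjusted p = 0.0141, and adjusted p = 0.873 with an estimated correlation). None of the 27 passed limma on its own, and 10 were higher at an unadjusted p under 0.05. In families that did not pass, the UDP-glycosyltransferase contig with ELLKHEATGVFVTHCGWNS rose by 2.48 (SE 0.59, limma adjusted p = 0.0197, above every control on 3 of 4 arrays), a call that was lost with the slide as a block (+2.16, adjusted p = 0.172). A MYB-related contig with the SHAQKYF-type signature, a DNA-binding motif, rose by 0.70 (SE 0.20, limma adjusted p = 0.0409, above every control on 3 of 4 arrays), and this call was lost too (+0.74, adjusted p = 0.0981).

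These 6 of 21 families passed limma's camera in 1x salt, and with an estimated correlation 0 did, where 2 had an unadjusted p under 0.05. By fry, which asks whether a family's contigs move 1 way without reference to other contigs, the adjusted p was 0.0256 for EF-hands, 0.00391 for kinases and sugar transporters and 0.0165 for tubulins, but 0.337 for chlorophyll a/b-binding proteins and 0.208 for ubiquitin. Of families that did not pass limma's camera, 2 passed by fry, MYB-related proteins (adjusted p = 0.0220) and UDP-glycosyltransferases (adjusted p = 0.0371). Adjusted over the list alone, 8 EF-hand contigs, 4 kinases, 2 sugar transporters and 2 tubulins fell and 1 EF-hand contig rose. No scaling changed the sign of these 6 medians, but that of sugar transporters was as small as -0.64 and that of kinases as small as -0.18. The ubiquitin call was lost under normexp with the 75th percentile (adjusted p = 0.0591), without control replicate 2 (adjusted p = 0.0866) and without 1x salt replicate 2 or 3 (adjusted p = 0.0972 and 0.106). That of chlorophyll a/b-binding proteins was lost without 1x salt replicate 2 (adjusted p = 0.0853), and that of EF-hands without 1x salt replicates 1 and 2 together (adjusted p = 0.198). Without 1x salt replicates 3 and 4 together, sugar transporters, chlorophyll a/b-binding proteins and ubiquitin lost theirs (limma's camera, adjusted p = 0.05025, 0.198 and 0.113). Tubulins lost theirs in 14 of 29 settings, among them without control replicate 1 or 2, 1x salt replicate 1, 2 or 3 or 3x salt replicate 2 (adjusted p from 0.0506 to 0.0853). Within slide 3 the medians were -0.36 for EF-hands, -0.25 for kinases, -1.16 for sugar transporters, -0.10 for tubulins, -0.06 for chlorophyll a/b-binding proteins and +0.08 for ubiquitin. In a fit with the slide as a block, tubulins (median -0.34, adjusted p = 0.0519) and chlorophyll a/b-binding proteins (-0.07, adjusted p = 0.105) no longer passed limma's camera. The blocked medians of the other families were -0.42 for EF-hands, -0.29 for kinases, -1.08 for sugar transporters and +0.22 for ubiquitin. Single contigs lost more: of the 8 changed EF-hand contigs 2 kept their call with the block, both lower, and the contig with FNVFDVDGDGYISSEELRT was among those that lost it. Of the 2 sugar transporters 1 kept it, the contig with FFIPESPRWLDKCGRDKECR losing it (adjusted p = 0.0849), and of the 3 kinases and the 2 tubulins 0 did.

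Over all contigs, 5535 of 37210 changed in 1x salt (14.9%), 3456 higher and 2079 lower. The higher share, 62.4%, ran from 53.8% (median scaling) to 67.4% (normexp with the 75th percentile) under other scalings. At least 2-fold changes were more often falls, with 465 higher and 622 lower of 1087. Log2 fold changes of changed contigs had a median size of 0.58. The 4 values of the groups did not overlap for 17.9% of contigs, where chance gives 2.86%. The 8 rises ranked first by fitted change lay between +3.85 and +3.12, with 2 of them at background on some control arrays, and 7 of the 8 rose in 3x salt as well. Of the 8 falls ranked first, 3 were not well above background on any array of 1x salt and at least 11-fold to 16.6-fold lower, and the other 5 lay between -4.33 and -3.76, with 3 of them at background on some arrays of 1x salt. All 8 fell in 3x salt too. Within slide 3, the slide that held both groups, 5478 of the 5535 changed contigs (99.0%) kept their direction, at a slope of 0.774 on the pooled fold changes, in arrays on which the calls themselves rest. When the slide was a fixed block, 1240 contigs changed, 598 higher and 642 lower, with 1102 of them among the 5535. Leaving out control replicate 1, 2 or 3 gave 2710, 2759 and 2589 contigs, and leaving out 1x salt replicate 1 gave 10590. The main fit pools the spread over all groups, and 1x salt had the widest. A fit of the 8 arrays alone gave 2228 contigs.

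In 3x salt against control, EF-hand contigs were lower again. Of 14, 9 fell, 0 rose and 5 did not pass, with a median of -0.53 and a family median below every control on 4 of 4 arrays (limma's camera, adjusted p = 6.07e-04, and adjusted p = 0.621 with an estimated correlation). The contig with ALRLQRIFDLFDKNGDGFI fell by 1.76 (SE 0.20, limma adjusted p = 5.16e-04, lower in 4 of 4 arrays), and the one with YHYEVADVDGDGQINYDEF fell by 0.97 (SE 0.16, limma adjusted p = 0.00322, lower in 4 of 4 arrays). Sugar transporter contigs had a median of -1.87, below every control on 4 of 4 arrays (limma's camera, adjusted p = 0.00681, and adjusted p = 0.434 with an estimated correlation). The pair that had fallen in 1x salt fell here too, with log2 fold changes of -1.91 (SE 0.31) and -1.87 (SE 0.26). Of 8 kinase contigs 6 fell, 0 rose and 2 did not pass, with a median of -0.53, below every control on 4 of 4 arrays (limma's camera, adjusted p = 0.00631, and adjusted p = 0.434 with an estimated correlation). The kinase contig with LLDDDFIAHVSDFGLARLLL fell by 0.71 (SE 0.11, limma adjusted p = 0.00230, lower in 4 of 4 arrays). The 6 that fell include a contig with a stop codon before its signature, whose family is less certain.

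Tubulins fell in 2 of 3 contigs in 3x salt, with a median of -0.40, below every control on 4 of 4 arrays (limma's camera, adjusted p = 0.0279, and adjusted p = 0.621 with an estimated correlation). Of 5 contigs of thioredoxins, small proteins that reduce disulfides, 2 fell, and the median was -0.19, below every control on 3 of 4 arrays (limma's camera, adjusted p = 0.0155, and adjusted p = 0.621 with an estimated correlation). Those that fell encode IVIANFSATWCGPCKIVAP, with a log2 fold change of -0.53 (SE 0.10), and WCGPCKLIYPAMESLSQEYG, with -0.70 (SE 0.21). The UDP-glycosyltransferase contig with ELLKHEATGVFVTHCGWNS rose 5.64-fold (log2 SE 0.59, limma adjusted p = 0.0152, higher in 4 of 4 arrays), while the median of its 3-contig family, +0.87, did not pass limma's camera (adjusted p = 0.149). A cytochrome P450 contig with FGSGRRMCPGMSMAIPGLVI fell by 1.34 (SE 0.20, limma adjusted p = 0.00189, lower in 4 of 4 arrays), while its family did not pass. Of 4 contigs of aquaporins, the water channels of membranes, 1 fell, with a log2 fold change of -0.50 (SE 0.16, limma adjusted p = 0.0468, lower in 4 of 4 arrays), and the family median of -0.47 did not pass limma's camera (adjusted p = 0.0725), though it did under normexp with the 75th percentile (adjusted p = 0.0233) and without control replicate 1 (adjusted p = 0.0471). Of 9 contigs of dehydrins, proteins that accumulate in drying cells, 0 passed limma and 2 were higher at an unadjusted p under 0.05. Their median was +0.58, the highest was +2.41 with an SE of 1.06, and the family's adjusted p by limma's camera was 0.636. Chlorophyll a/b-binding contigs had a median of -0.02 (limma's camera, adjusted p = 0.602), but under quantile scaling, normexp with quantile scaling and the authors' table it was -0.11, -0.11 and -0.12, and the family passed as lower (adjusted p = 0.0366, 0.0119 and 0.0331). Rubisco small subunit contigs had a median of +0.20 (limma's camera, adjusted p = 0.192), which was as low as -0.03 under another scaling and so changed sign.

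Of 21 families, 5 passed limma's camera in 3x salt, and 0 did with an estimated correlation, where 2 had an unadjusted p under 0.05. The largest adjusted p of these 5 by fry was 0.0187, and 3 other families passed by fry: histones (adjusted p = 0.0220), MYB-related proteins (adjusted p = 0.0247) and UDP-glycosyltransferases (adjusted p = 0.0392). Adjusted over the list alone, 10 EF-hand contigs, 6 kinases, 3 sugar transporters, 2 tubulins and 2 thioredoxins fell, and 1 kinase contig rose. No scaling changed the sign of these 5 medians, but that of sugar transporters was as small as -0.67 and that of kinases as small as -0.30. Within slide 2 alone thioredoxins did not pass (adjusted p = 0.0746), and in a fit of the 8 arrays alone tubulins did not (adjusted p = 0.0602). Without 1x salt replicates 3 and 4, thioredoxins and tubulins did not pass either (limma's camera, adjusted p = 0.05025 and 0.0674). All 5 passed with the slide as a block, with medians of -0.51, -0.48, -1.68, -0.40 and -0.18 for EF-hands, kinases, sugar transporters, tubulins and thioredoxins. In the same order the medians were -0.55, -0.46, -1.74, -0.58 and -0.12 within slide 2, and -0.35, -0.55, -1.19, -0.07 and -0.37 within slide 3.

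**Figure D2:**
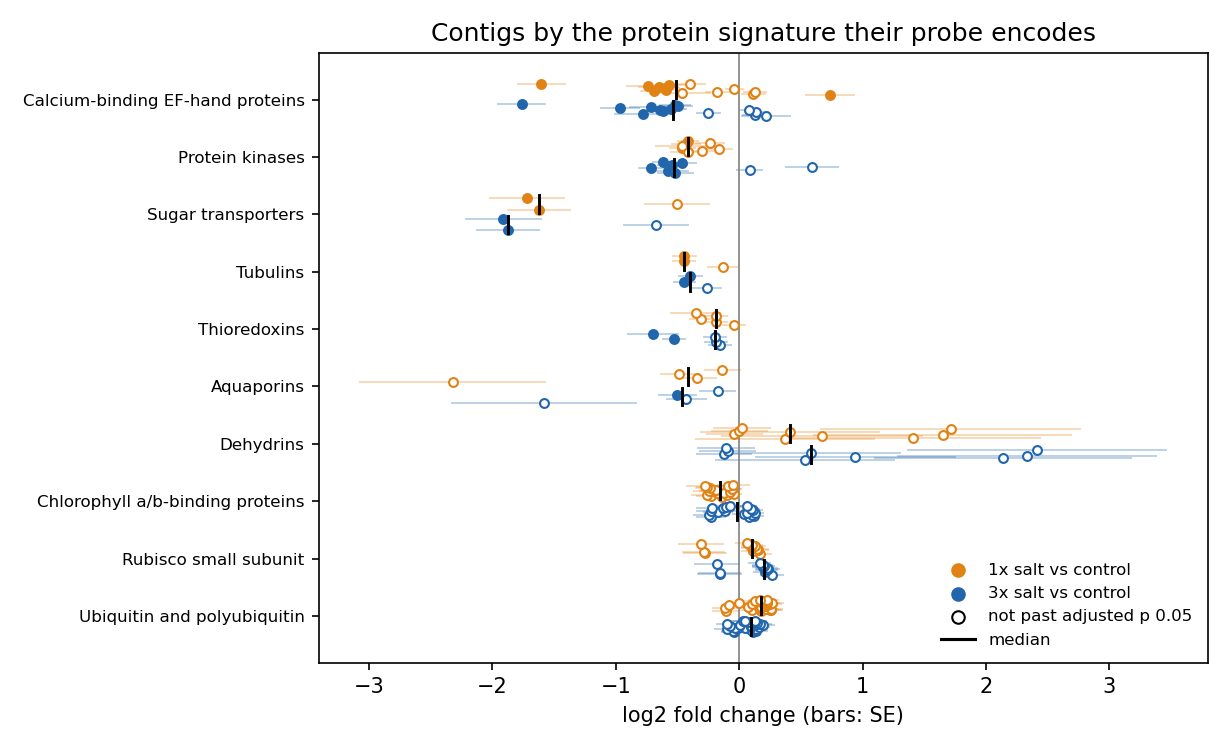
Each point is 1 contig, placed by its log2 fold change against control on the x axis with a bar for its SE, in rows by the protein signature its probe encodes, for 1x salt (orange) and 3x salt (blue). Filled points passed an adjusted p of 0.05, black ticks are medians, and EF-hand medians lie at -0.51 and -0.53 while dehydrin points spread up to +2.41 with wide bars.

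Over all contigs, 6891 of 37210 changed in 3x salt (18.5%), 4125 higher and 2766 lower, and 1572 of them by at least 2-fold, 659 higher and 913 lower. The higher share of all changed contigs, 59.9%, depended on scaling. It ran from 51.3% (authors' table), nearly even, to 66.5% (normexp with the 75th percentile). Log2 fold changes of changed contigs had a median size of 0.59. Groups did not overlap for 33.1% of contigs, where chance gives 2.86%. Of the 8 rises ranked first by fitted change, 6 were not well above background in any control and at least 10.6-fold to 56.5-fold higher, and the other 2, at background on some control arrays, had log2 fold changes of +8.30 and +4.34. Of the 8, 1 also rose in 1x salt. Of the 8 falls ranked first, 2 were not well above background on any array of 3x salt and at least 9.20-fold and 23.6-fold lower, and the other 6 lay between -4.65 and -3.43, with 4 of them at background on some arrays of 3x salt. All 8 fell in 1x salt too. Within slide 2 alone 7076 contigs passed, 4624 of them among the 6891. Of 7074 of these with a value on every array, 6205 (87.7%) had the same direction within slide 3, on other arrays, and the differences within the 2 slides correlated at r = 0.664 across contigs. Blocking by slide gave 6228 contigs, 3621 higher and 2607 lower. Leaving out control replicate 1, 2 or 3 gave 4250, 4171 and 4040 contigs, and leaving out 3x salt replicate 3 or 4 gave 4523 and 4188. A fit of the 8 arrays alone, without the wider spread of 1x salt, gave 11509.

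Of the contigs named for 3x salt, thellun_all_rep_c3099 rose. Its probe is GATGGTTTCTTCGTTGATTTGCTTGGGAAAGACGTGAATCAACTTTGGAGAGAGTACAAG. Its log2 value was 0.64 ± 0.57 (SD, n = 4) in 3x salt and -7.66 ± 1.69 (SD, n = 4) in the controls, where 1 of 4 arrays was well above background. The fitted log2 fold change was +8.30 (SE 1.82, limma adjusted p = 0.0112, higher in 4 of 4 arrays), and it was +7.85 with the 3 dim controls set no lower than the lowest signal well above background. The other that rose was thellun_all_rep_c4077, with the probe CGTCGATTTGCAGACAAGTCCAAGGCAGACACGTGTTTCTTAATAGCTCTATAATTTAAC. It stood at -2.25 ± 0.36 (SD, n = 4) in 3x salt and was not well above background in any control, so that it was at least 56.5-fold higher (limma adjusted p = 0.0117, higher in 4 of 4 arrays). Neither passed in 1x salt (limma adjusted p = 0.270 and 0.388), and their differences between 3x and 1x salt did not pass (+5.26 and +4.94, limma adjusted p = 0.220 and 0.177). These differences passed in 2 of 27 settings for each contig, both of which left out 1x salt replicate 3. Of the 4 arrays of 1x salt, 2 held thellun_all_rep_c3099 well above background, and replicate 3 alone held thellun_all_rep_c4077 so, at -0.88. That replicate held both contigs highest, so a fit without it favours a difference. Without it thellun_all_rep_c3099 differed by +7.54 between 3x and 1x salt (limma adjusted p = 0.00323), with 1 of 3 arrays of 1x salt well above background. None of those 3 held thellun_all_rep_c4077 well above background, and it was at least 55.8-fold higher in 3x salt. Both rises against control passed with the slide as a block (adjusted p = 0.0244 and 0.0251). Within slide 2, where both contigs were not well above background in the 3 controls, they were at least 389-fold and 51.8-fold higher in 3x salt. Within slide 3 the change of thellun_all_rep_c3099 was +6.06, and thellun_all_rep_c4077 was at least 62.3-fold higher. With normexp the log2 change of thellun_all_rep_c3099 was +4.83. That of thellun_all_rep_c4077 was +2.71, smaller than its lower bounds, which rest on the main background correction and on a floor that is not a detection limit.

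Of the contigs named as falls, thellun_all_rep_c5158 has the probe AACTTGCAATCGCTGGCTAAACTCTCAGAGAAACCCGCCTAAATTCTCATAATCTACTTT. It stood at -3.74 ± 1.2 (SD, n = 4) in the controls and was not well above background in either salt group. It was at least 23.6-fold lower in 3x salt (limma adjusted p = 2.31e-04) and at least 16.6-fold lower in 1x salt (limma adjusted p = 0.00215), lower in 4 of 4 arrays of each. The other was thellun_all_c20617, with the probe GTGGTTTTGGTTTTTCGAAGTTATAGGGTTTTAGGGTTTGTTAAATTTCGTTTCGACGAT. Its log2 value was -2.42 ± 1.09 (SD, n = 4) in the controls, -6.40 ± 0.36 in 1x salt, where 3 of 4 arrays were well above background, and -7.07 ± 0.56 in 3x salt, where 1 of 4 was. Its log2 fold change was -3.98 in 1x salt (SE 0.47, limma adjusted p = 0.00215) and -4.65 in 3x salt (SE 0.47, limma adjusted p = 3.10e-04), lower in 4 of 4 arrays of each. In control replicate 4 both contigs were below the other controls, at -5.54 and -4.05. Both falls passed with the slide as a block in 3x salt (adjusted p = 7.86e-04 and 0.00135) and in 1x salt (adjusted p = 0.0311 for thellun_all_rep_c5158). Within slide 2, where both were not well above background in the 2 arrays of 3x salt, they were at least 47.6-fold and 40.4-fold lower. Within slide 3 thellun_all_rep_c5158 was at least 4.77-fold lower in 3x salt and at least 5.44-fold lower in 1x salt, and thellun_all_c20617 had log2 changes of -2.34 and -2.15. With normexp the log2 changes of thellun_all_c20617 were -2.13 in 3x salt and -2.02 in 1x salt. Those of thellun_all_rep_c5158 were -1.353 and -1.245, smaller than its lower bounds, which rest on the main background correction and on a floor that is not a detection limit.

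**Figure D3:**
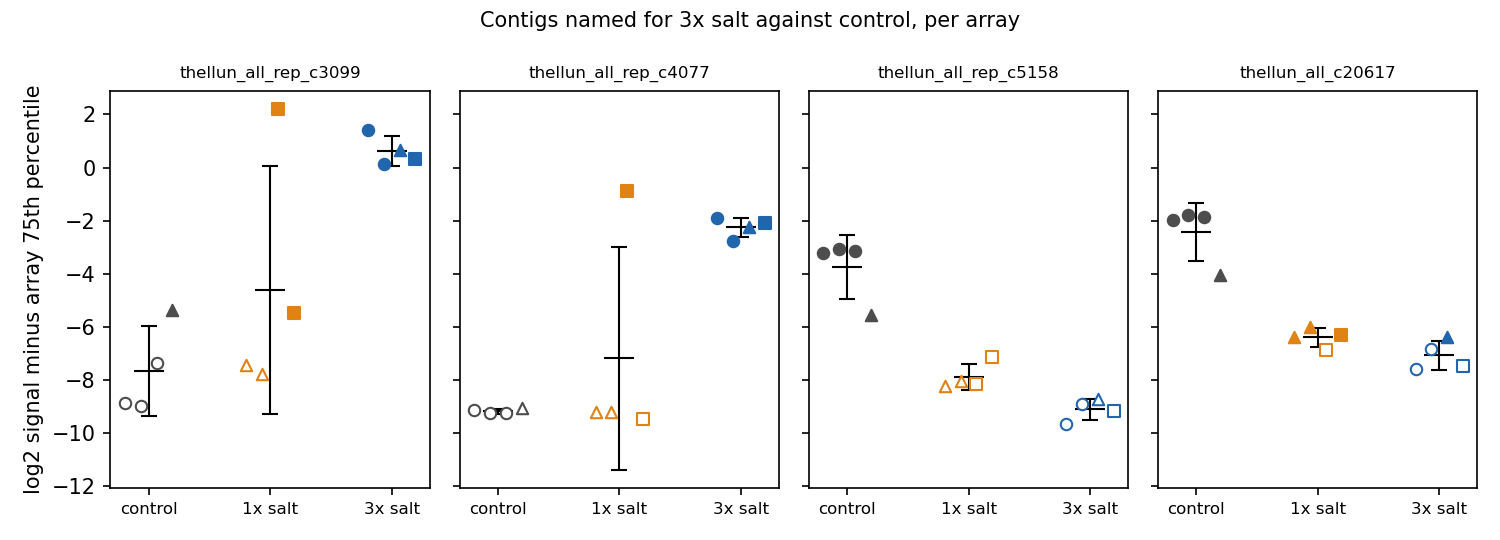
The y axis gives log2 signal minus the array's 75th percentile for the 2 contigs named as rises and the 2 named as falls in 3x salt, with 1 point per array (circles for slide 2, triangles for slide 3, squares for slide 1) and bars for the mean and SD of 4 arrays. Open points were not well above background, and 1 of the 4 arrays of 1x salt lies with 3x salt in both contigs that rose.

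Between 3x and 1x salt, few contigs passed the threshold. Of 37210, 339 changed (0.911%), 150 higher and 189 lower in 3x salt, and 135 by at least 2-fold, 62 higher and 73 lower. At an unadjusted limma p under 0.05 there were 5199. Simulated log2 changes of 0.5 were recovered in 0% for this comparison, so contigs that did not pass may still differ. Chlorophyll a/b-binding contigs had a median of +0.15 and ubiquitin contigs one of -0.10, beyond every 1x salt array on 0 of 4 and 2 of 4 arrays of 3x salt. By limma's camera both passed (adjusted p = 0.00732 and 0.00811), and neither did with an estimated correlation (adjusted p = 0.873 with an estimated correlation for both). On their own 0 of 18 and 0 of 27 passed limma, where 6 and 0 had an unadjusted p under 0.05. EF-hand, sugar transporter and kinase contigs had medians of -0.02, -0.19 and -0.16, with 0 changed, and their adjusted p by limma's camera was 0.513, 0.528 and 0.528. Without 1x salt replicate 1, EF-hands passed as lower in 3x salt (adjusted p = 0.0318). Among contigs with a signature, 1 changed: 1 of 2 contigs of DEAD-box RNA helicases, enzymes that unwind RNA, rose by 0.72 (SE 0.12, limma adjusted p = 0.0209, higher in 4 of 4 arrays), and with the slide as a block it did not pass (+0.68, adjusted p = 0.0696). Its translated probe has stop codons after the signature, so its family is less certain.

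For chlorophyll a/b-binding proteins and ubiquitin between 3x and 1x salt, the adjusted p by fry was 0.440 and 0.512, and adjusted over the list alone 0 contigs of either passed limma. No scaling changed the sign of these medians, which ran from +0.06 to +0.15 and from -0.16 to -0.10. The call of chlorophyll a/b-binding proteins was lost under quantile scaling, normexp with quantile scaling and the authors' table (adjusted p = 0.174, 0.171 and 0.102) and without 1x salt replicate 2 or 4 (adjusted p = 0.102 and 0.0966). That of ubiquitin was lost without 1x salt replicate 2 or 3 or 3x salt replicate 3 (adjusted p = 0.123, 0.149 and 0.0981). Blocking by slide gave medians of +0.10 (limma's camera, adjusted p = 0.104) and -0.12 (adjusted p = 0.0148). Within slide 1 they were +0.16 and -0.16, and within slide 3 +0.02 and -0.20. The 8 rises ranked first by fitted change lay between +4.42 and +3.43, with 3 of them at background on some arrays of 1x salt. Of the 8 falls ranked first, 1 was not well above background on any array of 3x salt and at least 3.12-fold lower, and the other 7 lay between -2.34 and -1.78, with 2 of them at background on some arrays of 3x salt. Groups did not overlap for 7.69% of contigs, where chance gives 2.86%. The differences within slide 1 and within slide 3, on different arrays, correlated at r = 0.338 across contigs, and 201 contigs changed when the slide was a block, 75 higher and 126 lower, with 137 of them among the 339. Leaving out 1x salt replicate 1 gave 1665, 1x salt replicate 2 gave 192, control replicate 3 gave 207, and 3x salt replicates 1 to 4 gave 92, 176, 57 and 70. The 8 arrays of this comparison alone gave 36. Of families, 5 passed limma's camera without 1x salt replicate 1, 0 without replicate 2, and 1 without replicate 3, replicate 4 or 3x salt replicate 3.

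Many contigs changed in both 1x and 3x salt. Of the contigs changed in either, 3437 changed in both, 3433 of them in the same direction, with 2075 up and 1358 down. These included 7 EF-hand contigs, 2 sugar transporters, 3 kinases and 2 tubulins, all lower in both. Across contigs, which are not independent replicates, the log2 fold changes correlated at r = 0.787 with a covariance of 0.187. Both comparisons share the control arrays, and simulated unchanged groups against the same controls gave r = 0.501 and a covariance of 0.0214. All simulated groups had equal spread, whereas the median SD was 0.140 in the controls, 0.230 in 1x salt and 0.127 in 3x salt. Simulated values are therefore rough benchmarks. The covariance exceeded the simulated one by 0.165. Unchanged groups give hardly any calls, so their 0 shared calls say nothing about overlap. Independent lists would share 383 contigs up and 155 down, but lists with the same controls are not independent. With the controls split into 2 and 2, r was 0.687 on average over 6 assignments (0.615 to 0.735), with a covariance of 0.171. On average 294.2 contigs up and 312.5 down were then shared, where independent lists would share 36.7 and 18.6. Blocked by slide, r was 0.75 with a covariance of 0.180, against 0.558 and 0.0333 in simulated unchanged groups. Within slide 3, which held 1 control array, r was 0.513, where simulated unchanged groups gave 0.577, and the covariance was 0.116, against a simulated 0.0856. With equal spread in these simulations, they cannot tell whether the responses within slide 3 share more or less than unchanged groups would. Changed in 3x salt but not past the threshold in 1x salt were 3454 contigs, and the difference between 3x and 1x salt itself passed for 208 of them. For the 2098 contigs changed in 1x salt but not past the threshold in 3x salt, it passed for 72.

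**Figure D4:**
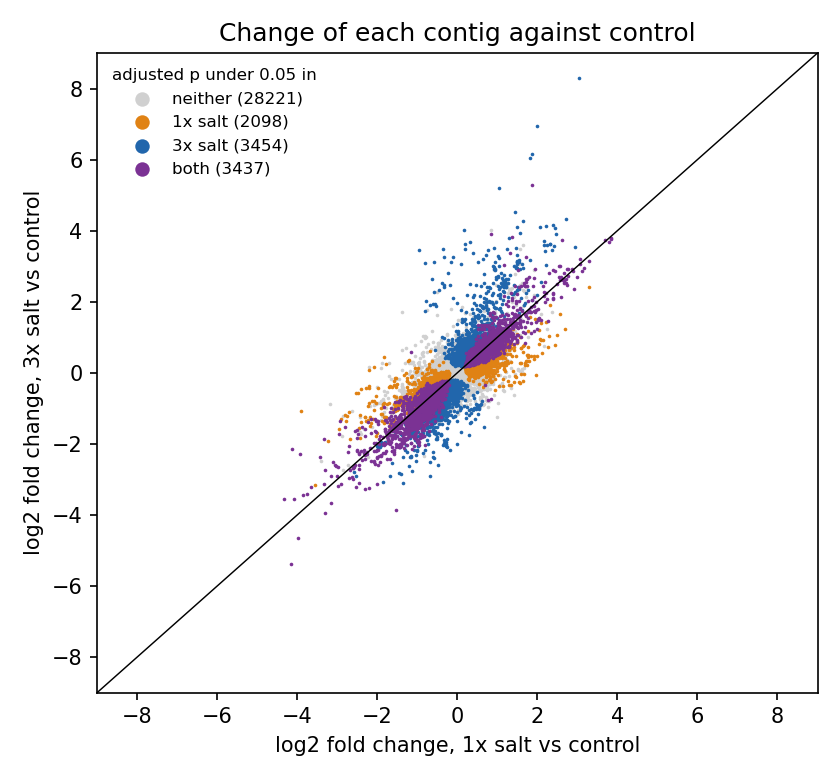
Each point is 1 contig, with its log2 fold change in 1x salt against control on the x axis and in 3x salt against control on the y axis, coloured by where its adjusted p was under 0.05, and the line marks equal changes. Of the 3437 contigs changed in both, 3433 have the same sign on both axes.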

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

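Chosen after the results were seen were the tests of a slide effect common to the groups, of a different extent of 1 salt response, of a slide effect in control replicate 4 and of the slide for EF-hand contigs, all EF-hand tests in 1x salt, and the fits that leave out a pair of 1x salt arrays.

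In each group of 4 arrays, the highest and lowest values of quality measures, family medians and named contigs were set against the other 3. Of 93 such groups, 12 held a value far from the rest, where chance gives about 1 in 20 (4.7 of 93). Control replicate 4 stood apart in 4 measures. Its tubulin contigs had a median of 0.0224 relative to their mean over arrays (log2), against 0.331 to 0.358 in the other controls. It held thellun_all_c20617 at -4.05, against -1.99 to -1.79, and thellun_all_rep_c5158 at -5.54, against -3.21 to -3.07. Its negative control spots had a mean net signal of 12.75 units, against 13.87 to 13.91 in the other controls, all on slide 2. The salt arrays of slide 3 had 12.45 to 12.81, so this value went with the slide. In 1x salt, replicate 1 had chlorophyll a/b-binding contigs at a median of 0.178, against -0.232 to -0.172, and thioredoxins at 0.168, against -0.131 to -0.0837. Replicate 3 of 1x salt held thellun_all_rep_c4077 at -0.88, against -9.46 to -9.20 on arrays not well above background. Replicate 4 held thellun_all_rep_c5158 at -7.15, against -8.21 to -8.04, with all 4 arrays not well above background. Small GTPase contigs lay at -0.0350 in control replicate 1, against 0.0688 to 0.0848, and SAUR contigs at 0.0904 in control replicate 2, against -0.265 to -0.209. Control replicate 3 had 309 outlier spots, against 269 to 275. The slope of spike-in signal on amount was 0.935 in 3x salt replicate 2, against 0.988 to 0.997.

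Other splits of the 8 arrays of each comparison into 4 and 4 were tested with limma. For 1x salt against control 1 of 35 splits, the real one, gave as many as its 5535 contigs, with 1845 in the highest other. For 3x salt against control 1 of 35 gave as many as its 6891, with 0 in the highest other. A rank of 1 in 35 is the best that these splits allow, which makes chance unlikely for both but does not exclude it. The splits took no account of slides. Slide 2 held 3 controls and no array of 1x salt, so they cannot tell salt from slide in that comparison. For 3x against 1x salt 2 of 35 splits gave as many as the real 339, so chance cannot be excluded. The other one gave 565 contigs and set 1x salt replicates 1 and 2 with 3x salt replicates 2 and 3 against the rest, which follows slides 3 and 1 for 6 of the 8 arrays. With the slide as a block, 201 contigs changed.

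The 1x salt arrays of slide 1 and slide 3 stood apart. Against a different extent of 1 salt response, the slide 1 minus slide 3 difference in 1x salt correlated at 0.102 across contigs changed in 3x salt with the 3x salt change. A slide effect common to the groups stays open: the same difference in 3x salt had a slope of 0.213 (spread 0.126) on it, below the 0.617 that a fully shared effect would give, but 3x salt had 1 array on each slide, and a partly shared effect is not excluded. Different content of mesophyll cells, whose markers guard cells also express, stays open too, with medians of the difference of -0.203 (spread 0.193) for chlorophyll a/b-binding and -0.198 for Rubisco small subunit contigs. A biological difference between these samples was not tested.

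With the slide as a block fewer contigs changed in 1x salt, 1240 in place of 5535. Blocked log2 fold changes had a slope of 0.972 on unblocked ones over the 5535 contigs, and the median SE grew by a factor of 1.19 (0.949 in 3x salt), so wider errors with few arrays that bridge slides may account for part of the loss. Whether they account for all of it was not tested. The contigs were chosen in the unblocked fit on the same arrays, and within slide 3 their slope was 0.774. A slide effect in control replicate 4 stays open, since the slide 3 minus slide 2 difference in 3x salt had a slope of -0.286 on that in the controls, with 1 array of each group on slide 3. The control difference correlated at 0.443 across contigs with the 1x salt change, where unchanged groups simulated in the same layout of arrays gave -0.0279 to 0.0348.

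For EF-hand contigs, lower in both salt groups, the tests argue against scaling, since under 5 other scalings the median stayed at least as low as -0.472 in 1x salt and -0.532 in 3x salt relative to all contigs. Median scaling shifts all contigs of an array alike and could not change this measure, so only the other settings inform. They argue against slide as the whole cause, since the blocked median kept 0.955 of its size in 3x salt and 0.82 in 1x salt, but 2 of 8 changed contigs kept their call in 1x salt, and a part due to slide stays open there. They argue against probe GC content and brightness, since 0 of 10000 matched random lists had a median as low in 1x salt (lowest -0.490) or in 3x salt (lowest -0.337), which gives 0.01%, the smallest share that 10000 lists can give. A change in these transcripts with salt is a hypothesis from the same data, and a change in the mix of cells was not tested for them. It may rest on fewer genes than 14, as 13 peptides are distinct and adjusted p = 0.621 with an estimated correlation.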

How the results depend on the processing

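Chosen after the data were seen were the family tests and the fits that leave out a pair of 1x salt arrays. The gene list tests and the description clause for named genes were not run as planned, because 0 contigs have a gene name. Counts are given in the order 1x salt against control, 3x salt against control and 3x against 1x salt, and main counts are 5535, 6891 and 339 contigs and 6, 5 and 2 families.

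Contig counts stayed within 1.5 times under quantile and median scaling, normexp, the authors' table, both filters on dim probes, the slide as a random block, the mean of a contig's probes and robust moderation. Array weights gave 10203, 15496 and 764 contigs, the 8 arrays of a contrast alone 2228, 11509 and 36, and a 2-fold threshold 1087, 1572 and 135. The main fit pools the spread over all groups, but median SDs were 0.140 in the controls, 0.230 in 1x salt and 0.127 in 3x salt. A fit of 8 arrays uses the spread of its own groups alone. Main p-values can thus be too small where 1x salt takes part and too large for 3x salt against control. The slide as a fixed block gave 1240 contigs in 1x salt and 201 between 3x and 1x salt. Without 1x salt replicates 1 and 2 the counts were 12484, 11425 and 5090, and without 1x salt replicates 3 and 4 the third was 1358. Families past the test numbered 0, 0 and 0 with an estimated correlation. Between 3x and 1x salt 1 passed, ubiquitin, under quantile scaling, normexp with quantile scaling, the authors' table and the slide as a fixed block, and 6 without 1x salt replicates 1 and 2. Without 1x salt replicates 3 and 4, 2, 3 and 0 passed. The correlation of the salt responses was 0.513 within slide 3 (0.577 in simulated unchanged groups of equal spread), 0.699 without 1x salt replicates 1 and 2 and 0.652 without replicates 3 and 4. For part of the loss in 1x salt with the slide as a block, wider errors may account (slope 0.972, but 0.774 within slide 3), and a slide effect in control replicate 4 stays open. A stricter threshold lowers counts, and fewer arrays can. Fewer arrays alone would not raise the count in 3x salt to 11509, and there the pooled spread may account. For the other settings the cause was not tested.

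With each array left out in turn, counts ran from 2589 to 10590, from 4040 to 9933 and from 57 to 1665, the correlation from 0.747 to 0.816, and families from 4 to 7, 5 to 6 and 0 to 5. In 1x salt control replicates 1, 2 and 3 (2710, 2759 and 2589) and 1x salt replicate 1 (10590) moved the count by over 1.5 times. In 3x salt control replicates 1, 2 and 3 (4250, 4171 and 4040) and 3x salt replicates 3 and 4 (4523 and 4188) did. Between 3x and 1x salt control replicate 3 (207), 1x salt replicates 1 and 2 (1665 and 192) and 3x salt replicates 1 to 4 (92, 176, 57 and 70) did. For families there, the count was 5 without 1x salt replicate 1, 0 without replicate 2, and 1 without replicate 3, replicate 4 or 3x salt replicate 3.

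The replicate number as a block gave 3995, 5305 and 120 contigs. The numbers did not pair the samples: deviations of 12 same-numbered pairs correlated at -0.257 to 0.395 across contigs, 3 of them over 0.1, and 7 of 24 best matches had the same number.

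The calls of the 4 named contigs in 3x salt passed in all 28 settings, and those of the 2 that fell passed in all 27 in 1x salt. The 65 calls of contigs with a signature kept their sign in every setting, and 42 stayed past the threshold with the slide as a fixed block (6 of 27 in 1x salt, 36 of 37 in 3x salt). Tubulins in 1x salt passed in 15 of 29 settings. Signals near background limit folds: under normexp thellun_all_c20617 changed by -2.02 in 1x salt in place of -3.98. There thellun_all_rep_c5158 changed by -1.245 in 1x salt (log2), where the main values gave at least 16.6-fold. In 3x salt thellun_all_rep_c4077 changed by +2.71 (log2) under normexp, where the main values gave at least 56.5-fold.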

Other observations

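Chosen after the data were seen were the family members named here and the positions of arrays along the 3x salt change.

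Families with 1 or 2 contigs were not tested as families, but some of their contigs changed. The contig with the GYWKATG signature of NAC transcription factors, plant regulators that include stress-related members, fell by 1.34 in 3x salt (SE 0.16, limma adjusted p = 7.46e-04) and had a log2 fold change of -0.89 in 1x salt (limma adjusted p = 0.00718). The translated probes of this contig and of the DEAD-box contig below have stop codons after the signature, so their families are less certain. A WRKY transcription factor contig with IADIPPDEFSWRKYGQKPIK had log2 fold changes of -0.58 in 1x salt (limma adjusted p = 0.0130) and -0.42 in 3x salt (limma adjusted p = 0.0381). A 14-3-3 contig with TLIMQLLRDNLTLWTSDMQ, of proteins that bind phosphorylated partners, had -0.49 in 1x salt and -0.46 in 3x salt (limma adjusted p = 0.0312 and 0.0318). In 3x salt a contig of PR-1, a protein linked to pathogen defence, with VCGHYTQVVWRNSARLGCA fell by 2.03 (SE 0.54, limma adjusted p = 0.0252), and a peroxidase contig with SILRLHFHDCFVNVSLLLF fell by 1.17 (limma adjusted p = 0.0174). In 3x salt an HSP70 chaperone contig rose by 0.44 (limma adjusted p = 0.0395), an R2R3 MYB contig by 0.48 (limma adjusted p = 0.0396) and a DEAD-box helicase contig by 0.84 (SE 0.12, limma adjusted p = 0.00152). A beta-glucosidase contig with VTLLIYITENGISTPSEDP rose by 0.61 in 1x salt (limma adjusted p = 0.0183). Each lay beyond every control on 4 of 4 arrays in the comparison given. With the slide as a block the NAC, 14-3-3 and beta-glucosidase contigs lost their call in 1x salt (adjusted p = 0.0616, 0.133 and 0.148), and the PR-1 contig lost it in 3x salt (adjusted p = 0.0576).

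Of the larger families, SAUR contigs, from a family of auxin-responsive genes, had medians of +0.00 in 1x salt, where the sign changed under other scalings, and +0.48 in 3x salt, with 1 of 4 having fallen in each, the contig with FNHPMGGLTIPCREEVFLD (log2 fold change -1.48 and -1.30, limma adjusted p = 0.0242 and 0.0337). Medians in 1x and 3x salt were -0.27 and -0.24 for ferredoxins and plastocyanins, -0.08 and -0.19 for histones and -0.07 and -0.07 for metallothioneins. They were -0.01 and -0.06 for papain-like proteases, -0.10 and -0.07 for small GTPases and -0.26 and -0.00 for RRM proteins. Contigs with the short LSGGQ signature, which need not all be ABC transporters, had +0.10 and -0.02, and cytochromes P450 had +0.30 and +0.42. None of these passed limma's camera in either, but with the slide as a block histones in 3x salt did (median -0.25, adjusted p = 0.0459, with 3 of 4 contigs having fallen), and by fry their adjusted p was 0.0220. In 1x salt small GTPases passed as lower under all 5 other scalings (adjusted p from 0.0224 to 0.0465), and ferredoxins and plastocyanins did under normexp with the 75th percentile (adjusted p = 0.0274) and without 1x salt replicate 1 (adjusted p = 0.00438). Under that normexp setting histones in 3x salt passed too (adjusted p = 0.0365). In 1x salt the medians of histones, metallothioneins and papain-like proteases changed sign under other scalings, as did that of RRM proteins in 3x salt. For cytochromes P450 the mean, -0.01 and -0.11, had the opposite sign to the median, as did the mean of SAUR contigs in 1x salt (-0.29) and of kinases between 3x and 1x salt (+0.02).

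Each array was placed along the change from control (0) to 3x salt (1), over contigs changed in a fit without that array. The 1x salt replicates 1 to 4 lay at 0.683, 0.572, 0.766 and 0.621, and the 3x salt replicates at 1.04, 0.874, 0.916 and 0.967. These contigs were chosen for their change in 3x salt, which favours higher positions there. Over contigs changed in both salt groups, the slope of 3x on 1x log2 fold changes was 1.02. Of those contigs, 52.5% had the larger change in 3x salt. Control replicates 1 to 3 lay at -0.00808, -0.0793 and 0.0125, and control replicate 4, on slide 3, lay at 0.308. Over contigs that differed by at least 4-fold, 16.7% had a value nearer to 3x salt in control replicate 4, against at most 1.49% in the other controls. Of 63 contigs that set 3x salt at least 4-fold apart from the other 1x salt arrays, 28 were nearer to 3x salt in 1x salt replicate 3, against 11 of 55, 6 of 41 and 11 of 45 in replicates 1, 2 and 4.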
